A study of Homo sapiens with 9 samples.

How the data were processed

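Gene expression was measured with Affymetrix arrays in subcutaneous tumours of HT29, a human colorectal adenocarcinoma cell line, carried by immunodeficient NOD/SCID mice. Per the labels, tumours developed over 14 days, treatment lasted 3 days and animals were killed 24 h after it ended. The labels name 3 groups of 3 arrays and call the arrays of a group biological replicates: vehicle, fluoxetine at 30 mg/kg/day and 5-fluorouracil at 50 mg/kg/day. Per the labels, total RNA was extracted on a QiaCube device and amplified and biotin-labelled with the IVT Express kit, which primes from the poly(A) end. No date, batch or housing detail was given in the sources used here.

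The authors deposited log2 values per probe set, made with RMA in R 3.0.1 per the submitters' processing notes. RMA subtracts background, brings all arrays to a common distribution and summarises the probes of each probe set, so differences in overall signal between arrays were removed before deposit. The package, the probe set definition and any filter were not given in the sources used here. The log2 scale was read from the values, which ran from 6.06 to 15 with array medians of 7.38 to 7.41. The lowest values sit far above 0, so changes of weakly expressed genes are compressed. Changes of genes near the highest values may be compressed as well.

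The table held 49395 probe sets, of which 102 were Affymetrix controls. In the platform annotation 44988 probe sets named 1 gene, 1832 named several and 2473 named none here. Probe sets naming several genes were left out. Symbols were checked through gene identifiers against the GRCh38.p14 gene table, used for names only. The identifiers of 44967 probe sets matched and 0 symbols changed. Each gene was represented by the probe set with the highest mean over all 9 arrays, which gave 18132 genes, with a median of 2 probe sets per gene. Genes were tested where that mean reached the 40th percentile of all probe set means, a log2 level of 7.11. This kept 12245 genes and removed 5887. The array is human, so signal from mouse stroma was not measured as such, and cross-hybridising mouse RNA could not be separated from tumour RNA.

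A linear model with 1 mean per group was fitted to all 9 arrays with limma 3.58.1 in R 4.3.3, using lmFit and eBayes with a trend in the variance. The fit had 6 residual degrees of freedom, or 14.7 with the prior. Each comparison used limma's 2-sided moderated test with Benjamini-Hochberg adjustment over the 12245 genes, and a gene passed at an adjusted p under 0.05. The comparisons were fluoxetine minus vehicle, 5-fluorouracil minus vehicle and fluoxetine minus 5-fluorouracil. Values are log2 differences with their standard error (SE) and group means with their standard deviation (SD, n = 3). With 3 arrays per group, their number limits the precision, and the median SE was 0.05. Tables were read with data.table (version 1.17.8) and plots drawn with matplotlib 3.10.9 in Python 3.11.15.

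Before the data were examined, 29 gene lists were fixed. They covered glycolysis, pentose phosphate and NADPH, the TCA cycle, oxidative phosphorylation, hypoxia, sterol synthesis, fatty acid synthesis, lysosome, p53 targets, DNA replication, mitosis, fluoropyrimidine and nucleotide metabolism, DNA repair and apoptosis. They also covered the unfolded protein and ATF4 response, heat shock and immediate early genes, ribosome biogenesis, ribosomal proteins, interferon response, NF-kB and chemokines, autophagy, serotonin signalling, intestinal differentiation, and Wnt and stem genes. Markers of fibroblasts and matrix, endothelium, leukocytes, red blood cells, and fat, muscle and skin stood for other cells that a subcutaneous tumour can hold. Each list was tested with camera at a preset correlation of 0.01 between genes, adjusted over the 29 lists, with camera at an estimated correlation and fry beside it. The fry value is printed only where its adjusted p was under 0.05, so a list given without it did not pass fry. Some listed genes were not analysed here, and counts refer to the members tested.

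Genes named in the text followed a rule fixed beforehand. In each comparison it took the 12 largest rises and the 12 largest falls among genes that passed and whose 3 arrays per group did not overlap. It added up to 4 members with the smallest p from each list described. It also added HK2, LDHA, SLC2A1, PKM, PDK1, TYMS, TYMP, DPYD, CDKN1A, MDM2, MKI67 and SLC6A4 in every comparison. Any other gene named was chosen after its values were seen, to identify small counts, to follow heat shock genes, or as a member of the clock gene set.

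On simulated values of 12245 genes with their observed means and variances, drawn independently of each other and tested for fluoxetine minus vehicle, the procedure called 82.1% of genes changed by 0.25 and 100% of those changed by 0.5 or 1 on the log2 scale. Of 199 simulated calls, 11 (5.53%) were of unchanged genes. A list of 30 genes shifted by 0.25 was found and 0 of 29 unshifted lists were called by camera. The simulated genes were independent, whereas the estimated correlation within the real lists reached 0.61. The simulation therefore cannot show how often lists of correlated genes are called falsely.

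The alternatives fixed beforehand were no filter and a stricter filter at the 60th percentile, the mean of all probe sets of a gene, eBayes without the trend, a fit of only the groups compared, quantile normalisation again, median centring, array weights, the replicate number as a block, a minimum change of 2-fold, and leaving out each array in turn. An alternative added after seeing the data used the 3′ minus 5′ difference of the beta-actin control probe sets as a covariate. All arrays stayed in every other fit. For lists called by camera, counts and ranges over 16 alternatives leave out the 2-fold minimum. They all use the preset correlation, so camera with an estimated correlation and fry are not among them.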

Results

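Transcript levels were compared in HT29 colorectal tumours carried by mice that received vehicle, fluoxetine or 5-fluorouracil, with 3 arrays per group and 9 arrays in all. Fluoxetine is an antidepressant that blocks the serotonin transporter, and 5-fluorouracil is a pyrimidine analogue used against colorectal cancer. The series title asks about fluoxetine and aerobic glycolysis, and the 5-fluorouracil group allowed a comparison with a standard cytotoxic drug. Arrays of a group correlated at r of 0.9975 to 0.9985 and arrays of different groups at 0.9938 to 0.9979. These correlations ran across all probe sets other than controls, which are not independent replicates. No array pair was identical (0 pairs). The first principal component held 43.7% of the variance and the second 17.9%.

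Control probe sets that report RNA quality differed between the groups. The beta-actin 3′ minus 5′ difference was 1.49 ± 0.10 (SD, n = 3) with vehicle, 1.03 ± 0.18 with fluoxetine and 0.91 ± 0.03 with 5-fluorouracil, on the log2 scale. For GAPDH it was 0.42 ± 0.02, 0.28 ± 0.04 and 0.28 ± 0.01 in the same order. The mean of the 18S ribosomal RNA controls was 13.62 ± 0.05, 13.84 ± 0.08 and 13.95 ± 0.11. Every comparison with vehicle therefore also compared arrays whose control transcripts had a larger 3′ excess with arrays where it was smaller.

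**Figure D1:**
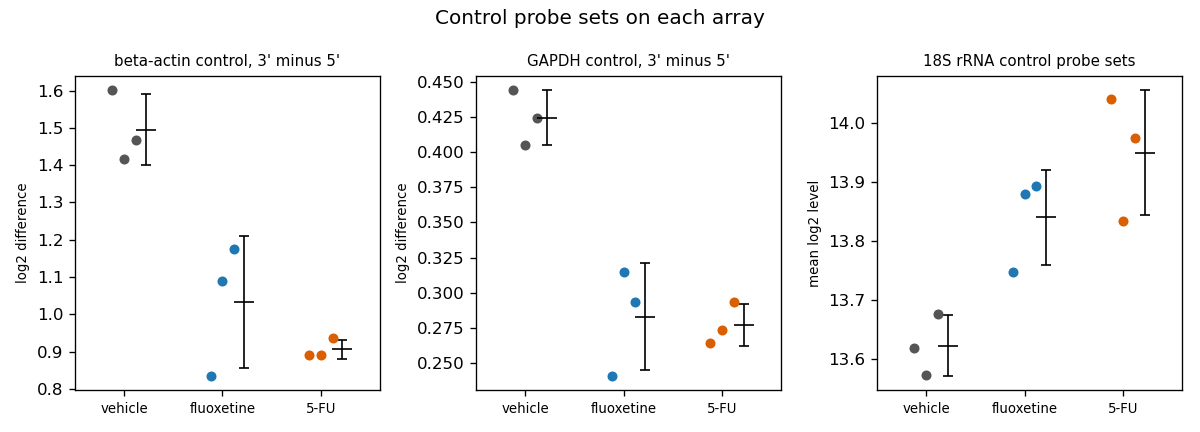
Log2 differences between 3′ and 5′ control probe sets of beta-actin and GAPDH, and mean log2 level of the 18S ribosomal RNA controls. Points are arrays (3 per group), and the bar beside them is the group mean with its SD; the vehicle arrays have the highest actin differences, with a mean of 1.49.

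In fluoxetine-treated tumours, several chaperone transcripts rose and a cold-inducible RNA-binding protein fell. EFEMP1, which encodes the matrix glycoprotein fibulin-3, rose 3.41-fold, from 8.14 ± 0.16 with vehicle to 9.91 ± 0.17 (SD, n = 3), a log2 change of 1.77 ± 0.18 (SE, adjusted p = 9.4e-05). It was the 1 gene of 1003 that changed at least 2-fold. CHORDC1, an Hsp90 co-chaperone, rose 1.92-fold (log2 0.94 ± 0.11), HSPH1, the Hsp110 chaperone, 1.73-fold (0.79 ± 0.08) and HSP90AA1, the inducible Hsp90, 1.63-fold (0.71 ± 0.07). CIRBP, the cold-inducible RNA-binding protein, fell by 0.75 ± 0.07 (adjusted p = 9.4e-05).

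Among the other large rises, CEMIP, which acts in hyaluronan turnover, gained 0.75 ± 0.08 and the zinc importer SLC39A10 0.62 ± 0.05. PPID, a further Hsp90 co-chaperone, rose by 0.62 ± 0.07. RSRP1 rose by 0.68, PHLDA1 by 0.66, the scaffold protein AKAP12 by 0.59 and KHDC4 by 0.56. A probe set annotated to the pseudogene HSP90AA4P rose by 0.69 and may share sequence with HSP90AA1. The falls included PUS7L (-0.83 ± 0.14), the histone gene H2AC20 (-0.76 ± 0.15), the nuclear noncoding RNA MALAT1 (-0.75 ± 0.13) and the corepressor SPEN (-0.75 ± 0.15). DEPTOR, an inhibitor of mTOR, fell by 0.58 ± 0.10 and the membrane mucin MUC17 by 0.52 ± 0.10. UHMK1 fell by 0.59, the pseudogene ZBED10P by 0.58, HDGF by 0.56, WASF2 by 0.54 and CDC42BPA by 0.53. For PUS7L, 1 other probe set moved the opposite way at an unadjusted p under 0.05. For EFEMP1, 1 of 4 probe sets carried the rise, the smallest change among them was 0.04, and the other probe sets lay under the filter level of 7.11. Leaving out 1 array ended the call in 5 of 6 fits for WASF2, in 4 for AKAP12 and in 1 each for H2AC20 and CDC42BPA.

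**Figure D2:**
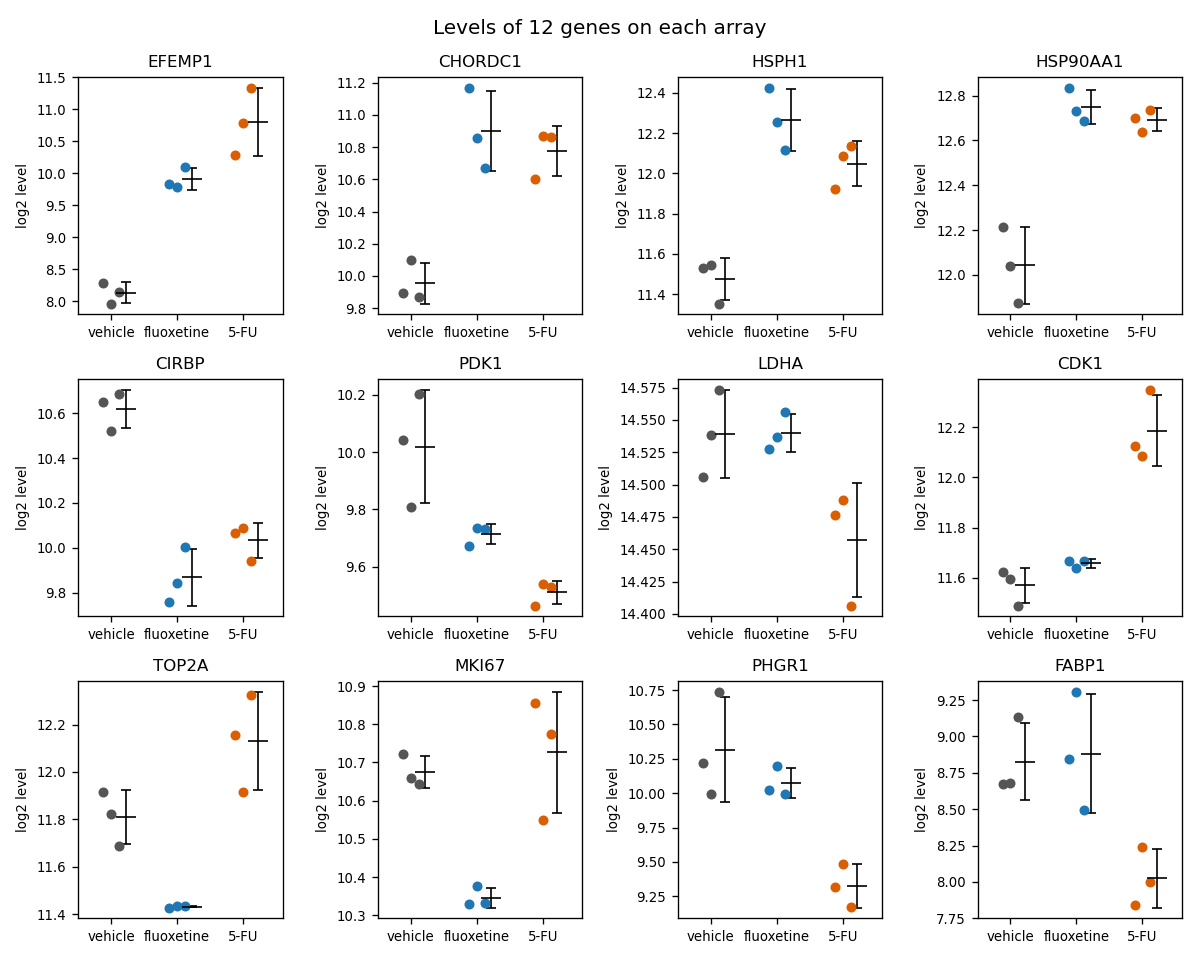
Log2 level of 12 genes on each array, on separate vertical scales. Points are arrays (3 per group), and the bar beside them is the group mean with its SD; EFEMP1 means were 8.14 with vehicle, 9.91 with fluoxetine and 10.80 with 5-fluorouracil.

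Heat shock and immediate early genes rose as a list with fluoxetine. Of 19 members tested, 8 rose, 0 fell and 11 did not pass; adjusted over the list alone, 9 rose and 1 fell. The list was called by camera (median log2 change 0.16, adjusted p = 2.3e-07), with adjusted p = 0.50 with an estimated correlation and 0.017 by fry. The members that rose were heat shock genes and MYC. They included HSPH1, HSP90AA1, the constitutive Hsp70 HSPA8 (0.43 ± 0.05) and its co-chaperone DNAJA1 (0.47 ± 0.05). With the actin 3′ minus 5′ difference as a covariate, an alternative added after seeing the data, the list had adjusted p = 1.5e-06 by camera. Over 16 alternatives at the preset correlation it ran from 3.4e-09 to 3.6e-06.

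The unfolded protein and ATF4 list also rose with fluoxetine, on the arrays with the smaller actin 3′ excess (1.03 against 1.49). Of 28 tested, 7 rose, 0 fell and 21 did not pass; 10 rose when adjusted over the list alone. The members that rose were DNAJB9, HSP90B1, HSPA5, MANF, PDIA4, PDIA6 and SDF2L1. ATF4 itself and ATF3, DDIT3, TRIB3 and ASNS did not pass. Camera gave a median of 0.11 and adjusted p = 7.2e-05, and adjusted p = 0.93 with an estimated correlation. The secreted endoplasmic reticulum protein MANF rose by 0.44 ± 0.08, the chaperone component SDF2L1 by 0.44 ± 0.10 and the disulfide isomerase PDIA6 by 0.26 ± 0.05. HSP90B1, the Hsp90 of the endoplasmic reticulum, rose by 0.21 ± 0.03, but 2 of its 7 probe sets moved the other way, and the mean of its probe sets was -0.04. The list median was 0.04 with the mean of probe sets, 0.02 with the actin covariate and 0.18 without fluoxetine 3. The SDF2L1 call ended in 4 of 6 fits without 1 array. The actin covariate gave adjusted p = 0.75, the highest of 16 alternatives at the preset correlation, of which the lowest was 9.6e-08.

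Glycolysis genes, the subject of the series title, showed no shift as a list. Of 22 tested, 0 rose, 1 fell and 21 did not pass, and 1 fell when adjusted over the list alone. The median change was -0.005 (camera adjusted p = 0.79; adjusted p = 0.94 with an estimated correlation). The 1 gene that fell was PDK1, the kinase that restrains pyruvate dehydrogenase (-0.31 ± 0.08, adjusted p = 0.025; means 9.71 ± 0.03 and 10.02 ± 0.20). PDK1 no longer passed without vehicle 1 (adjusted p = 0.089), vehicle 3 (0.083), fluoxetine 1 (0.11) or fluoxetine 2 (0.063). LDHA differed by 0.00 ± 0.03 (adjusted p = 0.99), the glucose transporter SLC2A1 by 0.02 ± 0.06 (0.86), PKM by -0.01 ± 0.08 (0.97) and HK2 by -0.08 ± 0.07 (0.58). LDHA ran from 14.51 to 14.57 on the vehicle and fluoxetine arrays, near the highest value of 15, where changes may be compressed. SLC6A4, the serotonin transporter, lay under the filter at 6.87 ± 0.04 with fluoxetine and 6.86 ± 0.01 with vehicle.

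Proliferation genes gave single falls rather than a list call. In the mitosis list, 1 of 29 rose, 3 fell and 25 did not pass; adjusted over the list alone, 1 rose and 5 fell. Camera gave a median of -0.08 and adjusted p = 0.061, with adjusted p = 0.94 with an estimated correlation. The proliferation marker MKI67 fell by 0.33 ± 0.07 (adjusted p = 0.0089), topoisomerase TOP2A by 0.38 ± 0.08 (0.013) and the spindle motor KIF11 by 0.19 ± 0.06 (0.047). CKS2, a partner of cyclin-dependent kinases, rose by 0.25 ± 0.07 (0.034). These arrays also had the lower actin 3′ minus 5′ difference, 1.03 against 1.49.

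Fibroblast and matrix markers, chosen to stand for cells other than the tumour line, were higher as a list. On this human array their signal may come from the tumour cells or from cross-hybridising mouse RNA, which could not be separated. Of 15 tested, 1 rose (COL1A1, 0.38 ± 0.08), 1 fell (COL4A2, -0.25 ± 0.06) and 13 did not pass; adjusted over the list alone, 4 rose and 1 fell. The median was 0.12 (camera adjusted p = 0.028; adjusted p = 0.93 with an estimated correlation). The call ended in 7 of 16 alternatives, with adjusted p from 0.0054 to 0.96. The median was 0.03 with no filter and 0.05 with probe set means or the actin covariate. The calls of COL1A1 and COL4A2 ended in 2 and 3 of 6 fits without 1 array. The list's adjusted p was 0.20 without vehicle 1, 0.0502 without fluoxetine 1 and 0.96 with the actin covariate. In the endothelial list 2 of 7 rose (ESAM and ENG, adjusted p = 0.50 by camera). In the leukocyte list 1 of 11 fell (CD74, 0.74), of red blood cell markers 0 of 2 changed (0.82), and of fat, muscle and skin markers 1 of 11 rose (CFD, 0.74). Adjusted over the list alone, 2 rose, 1 fell, 0 changed and 1 rose, in the same order.

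The other lists were not called for fluoxetine against vehicle. In metabolism, camera adjusted p-values were 0.15 for the pentose phosphate list (2 of 11 rose, PRPS1 and TIGAR), 0.75 for the TCA cycle (SUCLA2 and SDHD rose, IDH2 fell, of 21) and 0.81 for oxidative phosphorylation (CYCS rose, of 40). They were 0.81 for hypoxia (DDIT4 rose, of 19), 0.74 for sterol synthesis (0 of 19 changed) and 0.44 for fatty acid synthesis, where SCD (0.24 ± 0.05), ELOVL6 (0.32 ± 0.09) and ACACA (0.16 ± 0.05) rose among 10. The lysosome list had 1 fall of 27 (NAGLU, -0.42 ± 0.06; 0.080) and autophagy 3 of 24 (ATG13, WIPI2 and ATG12; 0.15). For p53 targets TIGAR and PPM1D rose and BBC3, DDB2 and XPC fell, of 25 (0.73). CDKN1A and MDM2 differed by -0.02 ± 0.06 and -0.07 ± 0.06.

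For DNA replication MCM10 rose and LIG1 fell, of 35 (camera adjusted p = 0.37), for DNA repair RAD51C rose, of 21 (0.34), and for apoptosis BIRC2 rose and TNFSF10 and CASP6 fell, of 18 (0.81). In the fluoropyrimidine list DCTPP1 rose, of 23 (0.81). TYMS differed by -0.08 ± 0.06, TYMP by 0.04 ± 0.05 and DPYD by -0.17 ± 0.08. Ribosome biogenesis had 4 rises, of POLR1A, WDR12, POLR1B and DDX21, and 1 fall, of NOP14, among 29 (0.34). Ribosomal proteins had 0 changes among 31 (0.81), interferon response 3 falls among 27 (IFIT3, CMPK2 and MX1; 0.18) and NF-kB and chemokines 1 among 16 (CXCL1; 0.37). Serotonin signalling had 0 changes among 5 (0.74). Intestinal differentiation had 1 rise, of CA2 (0.55 ± 0.09), and 4 falls among 25, of MUC13 (-0.43 ± 0.06), MUC1 (-0.46 ± 0.07), FCGBP (-0.50 ± 0.13) and MUC2 (-0.33; 0.73). The Wnt and stem list had rises of MYC and CCND1 and a fall of PROM1 among 14 (0.34); 1 other probe set of CCND1 moved the opposite way.

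Adjusted over the list alone, the rises and falls in these lists were 2 and 0 for pentose phosphate, 2 and 1 for the TCA cycle, 1 and 0 for oxidative phosphorylation, hypoxia and the fluoropyrimidine list, and 3 and 1 for fatty acid synthesis. For the lysosome they were 0 and 1, for autophagy 0 and 4, for p53 targets 2 and 5, for DNA replication 1 and 1, for DNA repair 4 and 0 and for apoptosis 2 and 3. For ribosome biogenesis they were 4 and 1, for interferon response 0 and 3, for NF-kB 0 and 2, for serotonin signalling 2 and 1, for intestinal differentiation 1 and 5 and for Wnt and stem 3 and 1. Sterol synthesis and ribosomal proteins had 0 of either. Each of these lists, and of the endothelial, leukocyte, red blood cell and fat, muscle and skin lists, had adjusted p = 0.94 with an estimated correlation. Median, mean and test did not share a sign for apoptosis, oxidative phosphorylation, sterol synthesis and endothelial markers.

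In all, 1003 of 12245 genes passed for fluoxetine against vehicle, 492 higher and 511 lower, with a median size of 0.25. The groups did not overlap for 27.7% of genes, where chance gives 10%. Leaving out fluoxetine 1, fluoxetine 2 or vehicle 1 left 373, 515 or 556 genes. Given the actin covariate, limma called 0. The covariate separates vehicle arrays (1.42 to 1.60) fully from fluoxetine arrays (0.83 to 1.17). With it the median SE grew to 0.12 and the median size of called genes shrank to 0.19. At an unadjusted p under 0.05 limma had 553 genes with the covariate, near the share of 0.05 that chance gives, and 2885 without it.

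In tumours treated with 5-fluorouracil, 22 of 29 mitosis genes were higher and 12 of 25 intestinal differentiation genes lower than with vehicle. Each list had adjusted p = 0.64 with an estimated correlation, and the intestinal list 0.063 with the actin covariate. EFEMP1 rose 6.33-fold, from 8.14 ± 0.16 with vehicle to 10.80 ± 0.52 (SD, n = 3), a log2 change of 2.66 ± 0.18 (SE, adjusted p = 3.5e-06), again in 1 of its 4 probe sets. CDK1, the kinase that drives entry into mitosis, rose 1.53-fold (0.62 ± 0.06, adjusted p = 1.0e-04). PHGR1 fell by 0.99 ± 0.14 (3.3e-04) and FABP1, the liver-type fatty acid-binding protein of enterocytes, by 0.80 ± 0.16 (0.0037).

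Further rises were of the exocytosis protein SYTL5 (0.83 ± 0.07), CHORDC1 (0.82 ± 0.11), the calcium-binding protein S100A2 (0.80 ± 0.06), PHLDA1 (0.80 ± 0.13) and the spindle protein FAM83D (0.77 ± 0.06). The cytidine deaminase APOBEC3B and the transcription factor MAF each rose by 0.74, the kinesin KIF18A by 0.68, and GDA, CTSV and HSP90AA1 by 0.65. LGALS2 fell by 0.93 ± 0.11, CCDC183 by 0.94 ± 0.12 and the goblet cell product FCGBP by 0.88 ± 0.13. DEPTOR fell by 0.81 ± 0.10, CSPG4 by 0.77 ± 0.09 and the intestinal annexin ANXA13 by 0.76 ± 0.14. SPEN and AKR1B10 fell by 0.75, MUC17 by 0.67 and the amino acid transport subunit SLC3A1 by 0.66.

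Mitosis genes rose most widely among the lists. Of 29 tested, 22 rose, 0 fell and 7 did not pass; 24 rose when adjusted over the list alone. The median was 0.32 (camera adjusted p = 3.4e-17; adjusted p = 0.64 with an estimated correlation; fry 0.022). Besides CDK1, the centromeric histone CENPA rose by 0.63 ± 0.07, cyclin CCNB1 by 0.52 ± 0.06 and the spindle midzone protein PRC1 by 0.43 ± 0.06. MKI67 differed by 0.05 ± 0.07 (adjusted p = 0.65). The actin 3′ minus 5′ difference was 0.91 on these arrays against 1.49 with vehicle.

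DNA replication genes rose in 15 of 35 cases, fell in 1 (the ligase LIG1, -0.20) and did not pass in 19; adjusted over the list alone, 16 rose and 1 fell. Camera gave a median of 0.15 and adjusted p = 8.1e-07, with adjusted p = 0.67 with an estimated correlation. The median was 0.08 without vehicle 3 and 0.23 with the actin covariate. Replication factor RFC4 rose by 0.36 ± 0.06, the licensing factor CDC6 by 0.42 ± 0.08, MCM10 by 0.37 ± 0.08 and UHRF1 by 0.26 ± 0.06. In the DNA repair list 7 of 21 rose, 0 fell and 14 did not pass; adjusted over the list alone, 8 rose and 1 fell. Its median was 0.14 (adjusted p = 2.0e-04; adjusted p = 0.64 with an estimated correlation; fry 0.022). The actin covariate moved that median to 0.23. The recombination gene RAD51C rose by 0.52 ± 0.06, BRCA1 by 0.37 ± 0.05, PARP1 by 0.33 ± 0.06 and the checkpoint kinase CHEK2 by 0.34 ± 0.06. The 18S controls averaged 13.95 on these arrays and 13.62 with vehicle.

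Genes that act on fluoropyrimidines or make deoxynucleotides gave 4 rises, 1 fall and 18 that did not pass, of 23; adjusted over the list alone, 6 rose and 2 fell. The median was 0.06 (camera adjusted p = 0.024; adjusted p = 0.67 with an estimated correlation). Thymidine kinase TK1 rose by 0.37 ± 0.07, the nucleotide hydrolase DCTPP1 by 0.39 ± 0.06, DCK by 0.28 ± 0.06 and RRM2 by 0.25, and the nucleotidase NT5C fell by 0.34 ± 0.06. TYMS, the enzyme that 5-fluorouracil inhibits, differed by 0.13 ± 0.06 (adjusted p = 0.16), TYMP by 0.02 ± 0.05 and DPYD, which degrades the drug, by 0.07 ± 0.08. The list call ended without vehicle 3 (0.14) or 5-fluorouracil 2 (0.16), with array weights (0.064) and with the actin covariate (0.12), and 16 alternatives ran from 0.0024 to 0.16. The median was 0.02 without vehicle 3 and 0.04 with the actin covariate.

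Intestinal differentiation genes fell in 12 of 25 cases, rose in 1 (CA2, 0.45) and did not pass in 12; adjusted over the list alone, 13 fell and 1 rose. The median was -0.27 (camera adjusted p = 2.2e-04; adjusted p = 0.64 with an estimated correlation). It was -0.16 without vehicle 3 or with probe set means, -0.18 with no filter and -0.13 with the actin covariate. The secreted mucin MUC2 fell by 0.64 ± 0.09, the goblet cell peptide TFF3 by 0.56 ± 0.09 and the membrane mucin MUC13 by 0.40 ± 0.06, besides FCGBP. The actin covariate gave adjusted p = 0.063, the highest of 16 alternatives at the preset correlation, of which the lowest was 3.6e-05.

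Interferon-stimulated genes fell in 10 of 27 cases, rose in 0 and did not pass in 17, with 10 falls also when adjusted over the list alone. The median was -0.16 (camera adjusted p = 7.3e-05; adjusted p = 0.67 with an estimated correlation). The antiviral GTPase MX1 fell by 0.52 ± 0.08, CMPK2 by 0.46 ± 0.07, RSAD2 by 0.34 ± 0.06 and IFI27 by 0.25 ± 0.05. Ribosomal protein transcripts fell by small amounts: 13 of 31 fell, 0 rose and 18 did not pass, and 24 fell when adjusted over the list alone. Their median was -0.11 (adjusted p = 6.6e-08; adjusted p = 0.67 with an estimated correlation; fry 0.036), with RPL6 at -0.17 ± 0.03, RPL11 at -0.17 ± 0.04, RPL37 at -0.14 ± 0.03 and RPL32 at -0.17 ± 0.04, the last no longer passing in 2 of 6 fits without 1 array. Quantile normalisation again moved the ribosomal median to -0.03. Both lists moved on arrays with the lower actin 3′ excess, 0.91 against 1.49.

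Hypoxia targets outside glycolysis fell in 6 of 19 cases, rose in 0 and did not pass in 13, with 6 falls adjusted over the list alone. The median was -0.11 (camera adjusted p = 0.014; adjusted p = 0.67 with an estimated correlation), but 0.24 was the adjusted p without vehicle 3, 0.056 without 5-fluorouracil 2 and 0.097 with array weights, in a range of 1.7e-04 to 0.24. The median was -0.19 without vehicle 2 and -0.05 without vehicle 3. The vasodilator ADM fell by 0.53 ± 0.10, MXI1 by 0.24 ± 0.06, CA12 by 0.25 ± 0.07 and BHLHE40 by 0.17 ± 0.05, the last turning to 0.05 with the actin covariate. Autophagy genes fell in 6 of 24 cases, rose in 0 and did not pass in 18, with 9 falls adjusted over the list alone. Camera gave a median of -0.08 and adjusted p = 0.034, with adjusted p = 0.67 with an estimated correlation. ATG13 fell by 0.31 ± 0.06, WIPI1 by 0.21 ± 0.05, WIPI2 by 0.23 ± 0.06 and BECN1 by 0.20 ± 0.05. This call ended without vehicle 1 (0.13) or 5-fluorouracil 2 (0.19), with the stricter filter (0.089), probe set means (0.27), array weights (0.13) and the actin covariate (0.37), and the lowest value was 0.0086. Its median was -0.12 without vehicle 2 and -0.05 with probe set means. Leaving out 1 array ended the calls of BHLHE40, WIPI2 and BECN1 in 4 of 6 fits each and of CA12 in 3.

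Heat shock and immediate early genes split with 5-fluorouracil: 7 of 19 rose, 2 fell and 10 did not pass, and 9 rose and 2 fell when adjusted over the list alone. The median was 0.11 (camera adjusted p = 0.0012; adjusted p = 0.64 with an estimated correlation; fry 0.036). That median was 0.22 without vehicle 1, 0.21 without 5-fluorouracil 2, 0.07 without 5-fluorouracil 3 and 0.18 with probe set means. The rises were of heat shock genes and MYC, with HSP90AA1 at 0.65 ± 0.07, HSPH1 at 0.57 ± 0.08, DNAJA1 at 0.41 ± 0.05 and HSPE1 at 0.33 ± 0.05. The falls were of the immediate early genes FOS (-0.39) and DUSP1 (-0.38). Fibroblast and matrix markers rose in 5 of 15 cases, fell in 0 and did not pass in 10, with 8 rises adjusted over the list alone. Their median was 0.14 (adjusted p = 2.0e-04; adjusted p = 0.64 with an estimated correlation; fry 0.022), and 0.38 with the actin covariate, in a range from 5.0e-05. The median was 0.05 with no filter, 0.04 with probe set means and 0.07 with the actin covariate. COL1A1 rose by 0.61 ± 0.08, COL3A1 by 0.55 ± 0.11, SPARC by 0.45 ± 0.08 and VIM by 0.45 ± 0.09, the last turning to -0.07 with the actin covariate. These arrays had actin 3′ minus 5′ differences of 0.91 ± 0.03 against 1.49 ± 0.10.

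**Figure D3:**
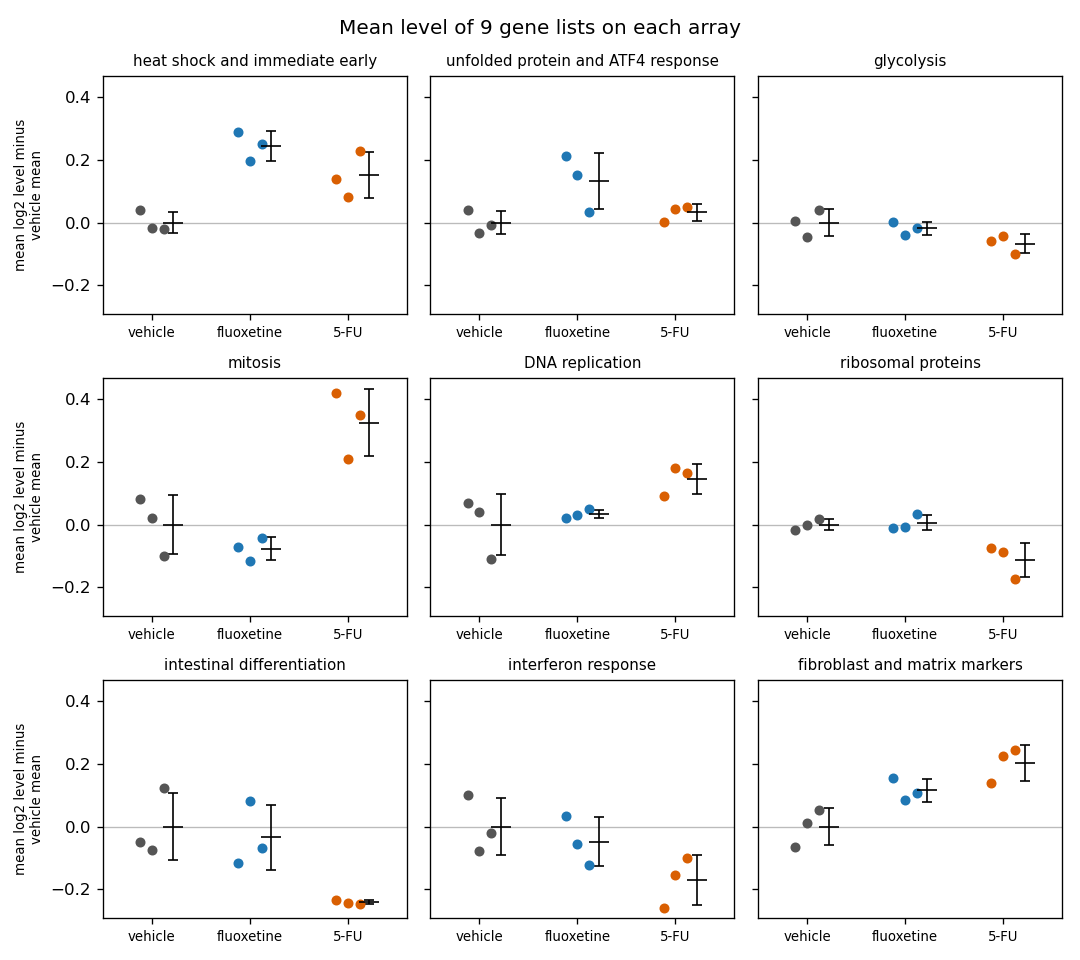
Mean log2 level of 9 gene lists on each array, minus the mean of the vehicle arrays. Points are arrays (3 per group), and the bar beside them is the group mean with its SD; the mitosis list is highest with 5-fluorouracil, where 22 of its 29 members rose.

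The remaining lists were not called for 5-fluorouracil. In glycolysis 3 of 22 fell (PDK1 by 0.51 ± 0.08, ALDOA by 0.18 ± 0.04 and GPI by 0.16 ± 0.05), 0 rose and 19 did not pass; 2 fell when adjusted over the list alone. The median was -0.06 (camera adjusted p = 0.20; adjusted p = 0.74 with an estimated correlation). LDHA differed by -0.08 ± 0.03, SLC2A1 by -0.15 ± 0.06, PKM by 0.15 ± 0.08 and HK2 by -0.15 ± 0.07, none of them passing, and the GPI call ended in 4 of 6 fits without 1 array. For p53 targets TIGAR (0.37 ± 0.06), PPM1D, PLK2 and FAS rose and BBC3 (-0.35 ± 0.06) and XPC fell, of 25; 4 rose and 2 fell adjusted over the list alone (0.63; adjusted p = 0.84 with an estimated correlation). CDKN1A, the p21 gene, differed by 0.03 ± 0.06 (adjusted p = 0.77) and MDM2 by -0.16 ± 0.06 (0.086). In the serotonin list the decarboxylase DDC (-0.42 ± 0.05) and the oxidase MAOA (-0.51 ± 0.10) fell and MAOB rose (0.18 ± 0.05), of 5. The same numbers passed when adjusted over the list alone, 1 up and 2 down (0.44; adjusted p = 0.67 with an estimated correlation; fry 0.022). In the apoptosis list PMAIP1 (0.54 ± 0.11) and BIK rose and TNFSF10 fell, of 18, also when adjusted over the list alone (0.63; adjusted p = 0.74 with an estimated correlation).

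In the TCA cycle list the succinate-CoA ligase subunit SUCLA2 (0.48 ± 0.06), IDH3A and SDHD rose and IDH2, SUCLG1 and SUCLG2 fell, of 21. Adjusted over the list alone, 3 rose and 4 fell (camera adjusted p = 0.73; adjusted p = 0.96 with an estimated correlation). The lysosome list had 6 falls of 27, led by NAGLU (-0.50 ± 0.06), or 8 adjusted over the list alone (0.078; adjusted p = 0.67 with an estimated correlation). Of NF-kB and chemokine genes CXCL8 alone rose (0.56 ± 0.14), of 16, on both adjustments (0.44; adjusted p = 0.67 with an estimated correlation). The unfolded protein and ATF4 list had 3 rises (PDIA6, PDIA4 and HSP90B1) and 1 fall (ATF4) of 28, or 1 rise adjusted over the list alone (0.18; adjusted p = 0.74 with an estimated correlation).

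In all, 2403 of 12245 genes passed for 5-fluorouracil against vehicle, 1000 higher and 1403 lower, with a median size of 0.23 and 1 gene, EFEMP1, at 2-fold or more. The groups did not overlap for 33.3% of genes, against 10% by chance. Leaving out 5-fluorouracil 3 or vehicle 3 left 1394 or 1599 genes. Given the actin covariate, limma called 0, with a median SE of 0.147 and a median size of called genes of 0.20. At an unadjusted p under 0.05 it had 681 genes with the covariate, near the share of 0.05 that chance gives, and 3961 without it.

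The drugs were then compared directly, a difference that leaves out the vehicle means, although the vehicle arrays enter its variance. The actin difference was 1.03 with fluoxetine and 0.91 with 5-fluorouracil. With fluoxetine 22 of 29 mitosis genes were lower, and of 25 intestinal differentiation genes 4 were higher, 1 was lower and 20 did not pass. These lists had adjusted p = 0.27 and 0.36 with an estimated correlation. TOP2A was lower by -0.70 ± 0.08 (SE, adjusted p = 5.0e-04; 11.43 against 12.13 ± 0.21, SD, n = 3). FABP1 was higher by 0.85 ± 0.16 (1.81-fold, adjusted p = 0.011) and PHGR1 by 0.75 ± 0.14. APOBEC3B was lower by -0.90 ± 0.10 and MKI67 by -0.38 ± 0.07 (adjusted p = 0.0070).

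Other genes higher with fluoxetine were CCDC183 (0.70), the intestinal lectin REG4 (0.59), the goblet cell products SPINK4 (0.53) and TFF3 (0.51), HOPX (0.49), DDIT4 (0.47), LGALS2 (0.46), ACSM3 and EDN1 (0.45 each) and FOS (0.44). Genes lower with fluoxetine included EFEMP1 (-0.89), the methyltransferase NNMT (-0.72), S100A2 (-0.70), C4BPB (-0.68), the mitotic kinase NEK2 (-0.65) and CTSV (-0.64). They also included SMC2, GGH and KIF18A (-0.59 each) and the kinetochore gene NDC80 (-0.58). The EFEMP1 difference did not pass without fluoxetine 1 (adjusted p = 0.062) or fluoxetine 2 (0.073), nor with probe set means (0.078) or only the groups compared (0.055). Leaving out 1 array ended the call in 5 of 6 fits for LGALS2, in 4 for SMC2, in 3 each for DDIT4, EDN1 and SPINK4, in 2 for PHGR1 and in 1 for FABP1.

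In the mitosis list 22 of 29 were lower with fluoxetine, 0 higher and 7 did not pass, and 29 were lower when adjusted over the list alone. The median was -0.39 (camera adjusted p = 3.1e-42; adjusted p = 0.27 with an estimated correlation; fry 0.012). DLGAP5 differed by -0.52 ± 0.06, KIF11 by -0.47 ± 0.06 and CDK1 by -0.53 ± 0.06. DNA replication had 3 lower of 35 (PRIM1, GINS4 and CDT1), or 7 adjusted over the list alone (adjusted p = 1.4e-08; adjusted p = 0.39 with an estimated correlation). DNA repair had 4 lower of 21 (BRCA1, FANCI, RAD54L and BLM), or 5 lower and 1 higher adjusted over the list alone (9.1e-05; adjusted p = 0.36 with an estimated correlation). In the fluoropyrimidine list TK1 (-0.46 ± 0.07), RRM2 (-0.41 ± 0.07) and DCK (-0.27 ± 0.06) were lower of 23, or 7 adjusted over the list alone (0.015; adjusted p = 0.48 with an estimated correlation). That call ended without 5-fluorouracil 2 (0.17), in a range from 0.0037, and the median turned from -0.02 to 0.01. The calls of CDT1 and BLM ended in 5 of 6 fits without 1 array, of GINS4, RAD54L and DCK in 4, of PRIM1 in 3, and of BRCA1 and FANCI in 1. TYMS differed by -0.20 ± 0.06 (adjusted p = 0.081).

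Ribosomal proteins were higher with fluoxetine in 3 of 31 cases (RPL3, RPL10A and RPL29), or 28 adjusted over the list alone, with a median of 0.12 (camera adjusted p = 1.6e-14; adjusted p = 0.36 with an estimated correlation). Intestinal differentiation had 4 higher of 25 (AGR2 at 0.35 ± 0.06, TFF3, FABP1 and SPINK4) and 1 lower (MUC1), or 11 and 1 adjusted over the list alone (median 0.23; adjusted p = 2.1e-05; adjusted p = 0.36 with an estimated correlation). The intestinal median was 0.14 without 5-fluorouracil 2, 0.13 without fluoxetine 2 and 0.12 with probe set means, and the ribosomal median 0.03 with quantile normalisation again. Array maxima were 14.73 to 14.88 with 5-fluorouracil and 14.91 to 14.99 with fluoxetine. The ribosomal list lies near these maxima, so its changes may be compressed. Hypoxia targets had 4 higher of 19 (DDIT4, CA12, ADM and BHLHE40), or 6 adjusted over the list alone (3.1e-04; adjusted p = 0.41 with an estimated correlation). Interferon response had 2 higher of 27 (IFI27 and IFI44L), or 8 adjusted over the list alone (3.1e-04; adjusted p = 0.52 with an estimated correlation), and 0.062 without fluoxetine 1, in a range from 2.0e-07. Single calls here were fragile: leaving out 1 array ended those of RPL10A and IFI44L in 5 of 6 fits, of RPL3, RPL29, ADM and BHLHE40 in 4, and of DDIT4 and SPINK4 in 3.

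The unfolded protein and ATF4 list had 0 of 28 members passing, or 9 higher adjusted over the list alone (camera adjusted p = 0.0050; adjusted p = 0.47 with an estimated correlation), and 0.14 without fluoxetine 1 and 0.096 with probe set means, in a range from 1.9e-06. In the heat shock and immediate early list FOS (0.44 ± 0.08) and HSPA1B (0.32 ± 0.07) were higher of 19, or 7 adjusted over the list alone (0.0097; adjusted p = 0.41 with an estimated correlation), but 0.19 without 5-fluorouracil 2 and 0.070 without fluoxetine 1, in a range from 4.7e-05. Of NF-kB and chemokine genes CXCL1 (-0.38 ± 0.07) and CXCL3 (-0.25 ± 0.06) were lower of 16, and 2 also adjusted over the list alone (0.0084; adjusted p = 0.32 with an estimated correlation; 0.061 with probe set means, in a range from 0.0012). Fibroblast markers had 0 of 15 passing on either adjustment (0.0099; adjusted p = 0.36 with an estimated correlation), and the call ended with probe set means (0.21) and the actin covariate (0.094), in a range from 0.0013. In serotonin signalling DDC (0.37 ± 0.05) and HTR1D (0.24 ± 0.06) were higher of 5, or 3 adjusted over the list alone (0.048; adjusted p = 0.36 with an estimated correlation; fry 0.012). That call ended in 9 of 16 alternatives, which ran from 0.018 to 0.68, and its median turned from 0.24 to -0.02 with no filter. The call of HTR1D ended in 5 of 6 fits without 1 array, of CXCL3 in 4, of HSPA1B in 3 and of CXCL1 in 1. The glycolysis list had 0 of 22 passing (median 0.05, 0.11; adjusted p = 0.62 with an estimated correlation).

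In all, 382 of 12245 genes differed between the drugs, 155 higher and 227 lower with fluoxetine, with a median size of 0.29, and 0 passed with a change of at least 2-fold. The groups did not overlap for 21.5% of genes, against 10% by chance, and 2166 genes had an unadjusted p under 0.05. The count was 108 without 5-fluorouracil 3, 673 without 5-fluorouracil 2, and 178, 125 and 195 without fluoxetine 1, 2 and 3; it was 793 with array weights, 265 with only the groups compared and 177 with the actin covariate.

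Most genes called for fluoxetine were also called for 5-fluorouracil against the shared vehicle arrays. In the same direction 711 genes passed in both, 330 higher and 381 lower, which is 70.9% of the fluoxetine calls and 29.6% of the 5-fluorouracil calls. Independent lists of these sizes would share 40.2 higher and 58.5 lower genes, figures that ignore the shared vehicle arrays. In 100 simulations of unchanged groups against shared vehicle arrays the shared count had a median of 0, and at most 5% of simulations lay above 0. Unchanged groups yield almost no calls, so this count was bound to be near 0. It cannot show how much of the overlap the shared arrays made. The log2 changes correlated at 0.72 across genes, within the simulated range, which had a mean of 0.45 and 5% of simulations above 0.86. Their covariance was 0.0124 against a simulated mean of 0.00178, a difference of 0.0106, with 5% of simulations above 0.00496. With 3 vehicle arrays no split leaves 2 on each side, so part of the excess may come from the shared arrays. The overlap was 292 without fluoxetine 1, 385 without fluoxetine 2, 412 without vehicle 1 and 459 without vehicle 3, and 0 with the actin covariate.

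In opposite directions 5 genes passed: FOXM1, HMGB2, KIF11, NDC80 and TOP2A, of which KIF11 and TOP2A belong to the mitosis list, were lower with fluoxetine and higher with 5-fluorouracil. They were named because of their small number, after their values were seen. FOXM1, a transcription factor of mitotic genes, fell by 0.21 ± 0.05 with fluoxetine and rose by 0.20 ± 0.05 with 5-fluorouracil. NDC80 fell by 0.19 ± 0.05 and rose by 0.39 ± 0.05, and TOP2A fell by 0.38 ± 0.08 and rose by 0.32 ± 0.08. Of the 287 genes called for fluoxetine alone, 41 differed between the drugs, and of the 1687 called for 5-fluorouracil alone, 257 did. Of the 711 shared genes 20 differed between the drugs, and 408 had the larger change with 5-fluorouracil.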

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

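The tests of fibroblast markers against endothelial and leukocyte markers, of random sets beside the clock genes and of the actin covariate were chosen only after the result was seen, as were the heat shock genes tested. The required marker level in the fibroblast test was added after a first version of that test had excluded the explanation.

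Control probe sets outside the comparisons rose above their vehicle level. With fluoxetine the 5′ beta-actin set rose by 0.28 on the log2 scale, the 5′ GAPDH set by 0.12, and the 3′, 5′ and middle 18S sets by 0.21, 0.17 and 0.27. With 5-fluorouracil the 5′ beta-actin set rose by 0.35, the 3′, 5′ and middle 18S sets by 0.42, 0.19 and 0.37, and the middle set of a further ribosomal RNA control by 0.25. The 3′ beta-actin set fell by 0.18 with fluoxetine and by 0.24 with 5-fluorouracil.

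The first pattern is the breadth of the difference between vehicle and treated arrays, 1003 and 2403 genes. A candidate explanation is lower RNA integrity on the vehicle arrays, since their actin 3′ excess was larger. Across the 711 shared genes, the change predicted from the slope on that excess within groups correlated with the observed change at 0.489, within the range of random covariates (-0.58 to 0.57; share as high 0.0755), so RNA integrity and treatment cannot be told apart here. With the covariate, calls ended as the median SE grew from 0.05 to 0.12 and 0.147 and the median size of called genes shrank from 0.25 to 0.19 and from 0.23 to 0.20; 96.9% and 92.6% kept their sign. The real split gave 1003, 2403 and 382 genes, in the order of the comparisons, 1 of 10 splits in each case, and the highest other split gave 0, 0 and 3; 10 splits are too few for a share under 0.05.

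The second pattern is the rise of heat shock genes with a fall of the cold-inducible genes CIRBP and RBM3 in both treated groups, a score of 0.91 (confidence interval at a 5% error rate 0.67 to 1.14) that adds both shifts, as the mean of 9 heat shock genes minus the mean of CIRBP and RBM3. With the same covariate the heat shock and immediate early list kept its camera call (adjusted p = 1.5e-06 with fluoxetine and 0.040 with 5-fluorouracil). Over 16 alternatives at the preset correlation camera gave 3.4e-09 to 3.6e-06 and 1.8e-04 to 0.040. The kept call cannot weigh against RNA integrity, since the covariate separates the vehicle arrays fully from the treated arrays and 0 genes passed with it. Single genes were mixed with 5-fluorouracil. The covariate moved HSPH1 from 0.57 to 0.25 and CIRBP from -0.59 to -0.26, but left HSP90AA1 at 0.64 and moved RBM3 from -0.28 to -0.38. None of these passed with it. With the covariate the score was 0.698 (-0.01 to 1.41). The list call also rests on a preset correlation (without the covariate, camera gave adjusted p = 0.50 and 0.64 with an estimated one). RNA integrity therefore stays open. A shift in time of day or body temperature between vehicle and treated animals may be another cause: 6 clock genes whose values had not been looked at moved in the direction of higher BMAL1 by 0.166 on average, and the share of 10000 random gene sets as high was 0.001; TEF fell with both drugs (-0.24 and -0.22), and NPAS2 differed by 0.03 and -0.005. The labels give no times, and an effect of the drugs on stress or clock genes was untested and stays open, so this is a hypothesis. The heat shock and immediate early list was fixed as one whose genes also move with tissue handling. A difference in handling between vehicle and treated tumours was not tested and stays open too.

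The third pattern is the higher fibroblast and matrix score with both drugs, 0.159 (0.07 to 0.25). A lower share of tumour cells could raise markers of all stroma, and the fibroblast score exceeded the endothelial and leukocyte score, which moved by 0.001 (-0.05 to 0.05), by 0.158 (0.08 to 0.23). It stays open because the endothelial and leukocyte markers had a median level of 7.45, nearer the background probe mean of 7.03 with vehicle than the fibroblast markers (8.07), although the mean levels were 8.02 and 7.97, and among markers at or below the median gene level of 8.78 (17 and 13, not matched in level) the difference was 0.126 (0.06 to 0.19). The pooled score joined lists that moved in opposite directions. With fluoxetine and 5-fluorouracil the mean change was 0.05 and 0.04 for 7 endothelial markers and -0.02 and -0.04 for 11 leukocyte markers. Of the 18 endothelial and leukocyte markers, ESAM rose (0.23 with fluoxetine and 0.22 with 5-fluorouracil) and CD74 fell with both drugs (-0.21 each). Under the actin covariate the fibroblast score was 0.0441 (-0.21 to 0.29), so RNA integrity is also open, and an effect of the drugs on matrix genes of the tumour cells was not tested.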

How the results depend on the processing

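The actin covariate was chosen after seeing the data; the other alternatives were planned. Gene counts moved by over 1.5 times in these settings. A minimum 2-fold change left 1, 1 and 0 genes for fluoxetine, 5-fluorouracil and the direct contrast, and an overlap of 1, since changes were small. With the actin covariate limma called 0, 0 and 177 genes (553, 681 and 1752 at an unadjusted p under 0.05), and the overlap was 0, with larger standard errors and smaller changes from vehicle. The 553 and 681 genes were near the share of 0.05 that chance gives. Array weights gave 793 genes in the direct contrast; the cause was not tested. Leaving out 1 array gave 373 (fluoxetine 1) to 911 genes for fluoxetine and 1394 (5-fluorouracil 3) to 2285 for 5-fluorouracil. Between the drugs it gave 108 (5-fluorouracil 3) to 673 (5-fluorouracil 2), and the overlap was 292 (fluoxetine 1) to 701. Fewer arrays were fitted, yet the count between the drugs rose from 382 to 673 without 5-fluorouracil 2, and the cause was not tested.

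With an estimated correlation 0, 0 and 0 of 29 lists were called, and by fry 1, 6 and 2, against 3, 11 and 13. For fluoxetine, quantile normalisation again called 5 lists, and leaving out 1 array 2 (vehicle 1) to 6 (vehicle 2). Leaving out 1 array, the glycolysis median ran from -0.026 to 0.022, turning positive without vehicle 3; it was -0.054 with the actin covariate, and it was not called. HSP90B1 for fluoxetine was -0.035 by the mean of probe sets, whose members disagree. With the actin covariate BHLHE40 was 0.053 and VIM -0.070 for 5-fluorouracil; the cause was not tested.

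Over the 27 list calls, 391 of 432 alternative values kept direction and call and 41 lost the call. These values all used the preset correlation. Camera with an estimated correlation, which is not among them, ended all 27 calls, and fry called 1, 6 and 2 lists. Over 209 named gene results, 2990 of 3536 values were the same, 469 lost the call, 44 gained it, 30 uncalled values changed sign and 3 reversed. With the replicate number as a block, 1037, 2438 and 428 genes and 4, 11 and 12 lists were called and the overlap was 734. The numbers gave no clear pairing of the arrays: over 9 same-number pairs r ran from -0.23 to 0.22, 3 above 0.1 and 1 below -0.1. Of 9 arrays, 5 correlated best with their own number, and so few arrays cannot exclude a pairing. The block ended the call of the serotonin list between the drugs (adjusted p = 0.054). Signal near 7 on the log2 scale limits what dim genes such as SLC6A4 (6.87) can show.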

Other observations

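The clock gene set was written after BMAL1, PER1, PER2 and DBP had been seen, and these are given as values only. BMAL1, an activator of the circadian clock, rose by 0.31 with fluoxetine and 0.40 with 5-fluorouracil (adjusted p = 0.0025 and 1.5e-04). Its targets PER1 and PER2, which act in the opposite phase, fell by 0.19 and 0.25 with fluoxetine and by 0.26 and 0.28 with 5-fluorouracil. DBP fell by 0.24 with 5-fluorouracil (0.019) and differed by -0.17 with fluoxetine (0.13). CLOCK rose by 0.22 with 5-fluorouracil (0.0043) and differed by 0.11 with fluoxetine (0.17). None of these genes differed between the drugs, with adjusted p-values from 0.21 for CLOCK to 0.87 for PER2, which does not show that they were alike.

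RBM3, like CIRBP a cold-inducible RNA-binding protein, fell by 0.40 ± 0.06 (SE) with fluoxetine and by 0.28 ± 0.06 with 5-fluorouracil. HSPE1, the mitochondrial co-chaperone, rose by 0.46 ± 0.05 and 0.33 ± 0.05, whereas its partner HSPD1 differed by 0.07 ± 0.06 in each. HSPB1 rose by 0.48 ± 0.09 and 0.44 ± 0.09. HSPA1B rose by 0.51 ± 0.07 with fluoxetine, differed by 0.20 ± 0.07 with 5-fluorouracil (adjusted p = 0.060) and was higher with fluoxetine than with 5-fluorouracil (0.32 ± 0.07, 0.026).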
